A study of Homo sapiens with 6 samples.

How the data were processed

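Gene expression was measured by RNA sequencing in HEK-293T cells, a human embryonic kidney line that carries the SV40 large T antigen. Per the labels' protocols, cells in 12-well plates received 300 µL of culture supernatant of the yeast form of Candida albicans (abbreviated YFCS) or the same volume of uninoculated yeast medium. The yeast, strain SC5314, had been cultured for 24 h at 30 °C in YPD broth to which gentamicin and chloramphenicol were added, and the supernatant was passed through a 0.22 µm filter. The labels spell the control medium both YPD and YFD, and the series' design text states that it was processed in the same way as the supernatant. Whether it also held the antibiotics is not stated. Exposure lasted 24 h, except that the description of YFCS replicate 3 gives 25 h while its protocol gives 24 h. Libraries were made with a SMARTER mRNA-Seq kit, per the labels' protocols. No label says whether the kit or the counting kept strand.

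The values used were the deposited estimated counts of reads per gene for all 6 libraries, in a single table, together with the deposited estimated transcript counts of the 3 control libraries. These counts were not normalized. The submitters' processing notes list the mouse builds GRCm38 and mm10, whereas the deposited gene identifiers are human Ensembl identifiers. The aligner, the counting program and the human annotation are not given in the sources used here. The table held 23342 features, of which 20463 carried an Ensembl identifier and 2879 an identifier beginning with MSTRG, a prefix that marks loci assembled from reads. In each of the 3 control libraries the gene count equalled the sum of the transcript counts for all 23342 features, after rounding. Reads of overlapping or near-identical genes can therefore be divided by an estimate. A further 12 columns of normalized or transcript values carried a sample code that matched no label and are not used here, so transcript-level comparisons were not analysed here.

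Total counts ranged from 23036631 to 30842030 per library. Every pair of libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom of 15.5 or more, so each was counted as a separate replicate. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Intervals cover counting error only.

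The groups were compared with edgeR version 4.0.16 in R version 4.3.3. Counts were rounded to whole numbers, low counts were removed with filterByExpr, and libraries were scaled by the TMM method. The quasi-likelihood F-test with robust dispersion was then run for YFCS minus control, two-sided, with 3 libraries per group and no covariate. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and a second count required a fold of 2 or more. Levels are given as CPM, the count scaled to library size after TMM scaling, as mean ± SD over 3 libraries, and log2 fold changes carry the standard error (SE) implied by the F statistic. After filtering, 16736 features were tested, 14834 of them with an Ensembl identifier.

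Before the data were examined, 34 gene lists, 8 lists of cell type markers, the tests, other settings to be tried and the rule for naming genes were fixed. Lists with 5 or more tested members were compared with all other genes by camera in limma version 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and adjusted over the lists. The same test with an estimated correlation, and fry, were run beside it. Named genes had a symbol, a mean CPM of 5 or more in a group and no overlap between the groups. They were the 10 with the largest increase, the 10 with the largest decrease and the 5 with the smallest p in each direction. Up to 4 changed members of each list, smallest p first, were added, or the 2 most abundant where none changed. Genes named outside this rule are marked as such, and 1 gene that met it is not reported here. Lists of intestinal epithelium and B lymphocyte markers were written after the gene test had been seen and before the values of their members were looked at.

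Positions, GC content and neighbouring genes were taken from GENCODE release 29 on GRCh38 by gene identifier. GC content was known for 88.1% of tested features and for 99.4% of those with an Ensembl identifier. A GC correction, added after the data were seen, removed from each library a lowess trend of log2 CPM on GC content with a span of 0.3. Settings fixed beforehand covered other size factors, other filters, DESeq2 version 1.42.0, a replicate block, and each library left out in turn.

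The gene test was tested on simulated data built from the means and library sizes of YFCS against control over 16427 genes. It recovered 30 of 66 genes changed 1.5-fold, 39 of 65 changed 2-fold and 49 of 61 changed 4-fold, with 17 false calls.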

Results

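The series asks how soluble products of yeast-form Candida albicans alter transcription in a human cell line. HEK-293T cells given filtered culture supernatant (YFCS) were compared with cells given uninoculated medium, with 3 libraries per group. The groups therefore differ in all that yeast growth changed in the medium, including any nutrients used up. Effects of products released by the yeast cannot be told apart from effects of such depletion here. The YFCS libraries held 23036631, 28155134 and 30842030 counts, and the control libraries 24203567, 23689398 and 24069003.

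Transcripts of MUC13, a transmembrane mucin, and of CXCR5, a chemokine receptor of lymphocytes, were present in every YFCS library and far lower in controls, which held few or no counts of CXCR5. All 13 mitochondrially encoded mRNAs fell, with a median log2 fold change of -0.88. By camera with a preset correlation of 0.01, targets of p53 and replication-dependent histone genes were higher as groups, and genes of cholesterol synthesis and of the extracellular matrix lower. With an estimated correlation these calls were lost, at an adjusted p = 0.0775 for p53 targets, 0.185 for histones, 0.185 for cholesterol genes and 0.281 for extracellular matrix. Most single changes were small, since the median fold among changed genes was 1.30. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 2287 features changed, 1079 higher and 1208 lower, of which 82 were assembled loci without an Ensembl identifier. A change of at least 2-fold was found for 129 features, 113 higher and 16 lower. The split depended on the test, since DESeq2 without a block gave 87 higher and 34 lower. The groups did not overlap for 36.8% of tested features, where chance alone gives 10%. Scaling by library size alone gave 1380 higher and 630 lower. The number of changed genes depended on the library left out: it was 1001 without YFCS replicate 1, 588 without YFCS replicate 2 and 423 without YFCS replicate 3. Among controls it was 1418 without replicate 1, 2108 without replicate 2 and 696 without replicate 3. Fewer libraries also leave fewer degrees of freedom, so the falls cannot be credited to the library left out alone. The 2-fold count was 63 without YFCS replicate 2, 60 without YFCS replicate 3 and 176 without control replicate 2. YFCS replicate 3 is the library whose description gives another exposure time.

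MUC13 (ENSG00000173702, chromosome 3, 124905442 to 124953819, minus strand) averaged 3114 ± 339 CPM in YFCS libraries and 5.32 ± 4.11 CPM in controls (SD, n = 3 each). Its counts were 66277, 97616 and 97387 in YFCS libraries against 42, 234 and 102 in controls, a ratio of 584 with a 95% counting interval of 528 to 648. CXCR5 (ENSG00000160683, chromosome 11, 118883766 to 118897799, plus strand) averaged 49.0 ± 2.40 CPM after YFCS. It had 1184, 1435 and 1459 counts there against 2, 0 and 0 in controls, a ratio of 1723 with a 95% counting interval of 477 to 14235. CXCR5 overlaps BCL9L in the annotation, so its counts are uncertain to that extent. The log2 fold changes were 9.19 (SE 0.68) for MUC13 and 10.53 (SE 0.39) for CXCR5, and both passed edgeR's test without any single library.

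**Figure D1:**
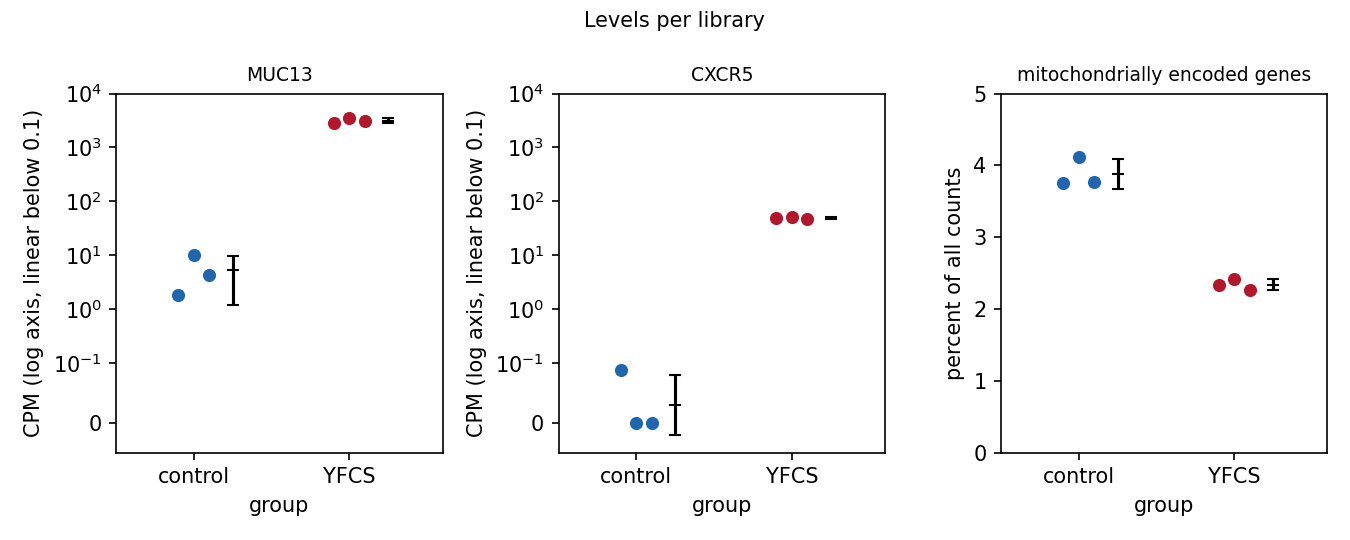
CPM of MUC13 and CXCR5 (log axis, linear below 0.1) and the percent of all counts from mitochondrially encoded genes, per library. Points are libraries, and bars show the mean and SD of 3. The groups do not overlap in any panel, and mitochondrially encoded genes took 2.34% of counts in YFCS libraries against 3.88% in controls.

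Among the other genes with a symbol and a mean of 5 CPM or more in a group, increases were smaller. Below that level or without a symbol, further features were near 0 in a group: 11 features, 8 of them assembled loci, had 10 or more counts in each YFCS library and 0 in every control, and 3 features showed the reverse. DNAH17, a dynein heavy chain of cilia, rose from 9.09 ± 0.18 to 28.6 ± 1.95 CPM (log2 fold change 1.65, SE 0.08). NPR3, the natriuretic peptide clearance receptor, rose by 1.64 on the log2 scale (SE 0.20). PPM1D, a phosphatase induced by p53, rose by 0.85 (SE 0.05) and EFL1, a ribosome maturation GTPase, by 0.76 (SE 0.06). The read-through genes DUS4L-BCAP29, TRIM59-IFT80 and RTEL1-TNFRSF6B also rose, but share sequence with the genes they span and are uncertain. Among genes of the same level, the largest decrease was in HLA-DPA1, which overlaps HLA-DPB1 and went from 12.8 ± 6.06 to 1.93 ± 0.42 CPM (log2 fold change -2.72, SE 0.37). RNF31 (-1.34) and ISM2 (-0.91) also fell. Among the smallest p-values were decreases of MYC, a growth-promoting transcription factor (-0.71, SE 0.05), GRN, which encodes progranulin (-0.73, SE 0.05), PRKCSH (-0.64, SE 0.05) and ICAM5 (-0.62, SE 0.05). In the annotation DNAH17 overlaps PGS1, RNF31 overlaps PSME2 and PRKCSH overlaps ODAD3, so their counts are uncertain to that extent. The same holds for other genes named below, among them TP53INP1, TGFB1 and COL4A2.

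Of the 33 fixed gene lists with enough members, 8 stood apart from other genes by camera. None did with an estimated correlation (5 at an unadjusted p under 0.05), nor with that and GC correction (6), while fry called 12, including those 8. The estimated correlation was 0.0032 for p53 targets and -0.012 for G2/M genes, below the preset 0.01. A higher correlation between genes is therefore not why those calls were lost. For p53 targets the unadjusted camera p still went from 1.69e-10 to 0.00235. Camera with an estimated correlation therefore differs from the preset form in more than the correlation. For the other called lists the estimate was 0.051 to 0.339, so their lost calls cannot be credited to correlation alone. All 8 were also called by camera without each library in turn.

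The mitochondrially encoded list was lower (camera adjusted p = 2.73e-11, and adjusted p = 0.185 with an estimated correlation). All 13 members fell, over all genes and adjusted over the list alone. MT-CO3, a subunit of cytochrome c oxidase, went from 2369 ± 248 to 1054 ± 76.7 CPM, and MT-ATP6, a subunit of ATP synthase, from 1322 ± 145 to 671 ± 21.1 CPM. MT-CYB fell by 0.68 on the log2 scale. These genes have nuclear pseudogene copies, and MT-ATP6 overlaps MT-ATP8 and MT-CO3, so the division of reads among them is uncertain. Nuclear genes of oxidative phosphorylation had a median of -0.08, and 2 of 56 fell, NDUFV1 (-0.48) and SDHA (-0.25). Camera did not call that list (adjusted p = 0.410) but called it lower without YFCS replicate 2 (median -0.14, adjusted p = 0.0391) and without control replicate 2 (median -0.14, adjusted p = 0.00658). These calls rest on the preset correlation of 0.01. The estimated correlation with all libraries was 0.758, with a camera adjusted p = 0.981.

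Of 26 tested p53 targets, 13 rose, none fell, and 18 rose adjusted over the list alone (median log2 fold change 0.40, camera adjusted p = 2.78e-09, and adjusted p = 0.0775 with an estimated correlation). Activity of p53 was not measured in this line, which carries the SV40 large T antigen, so the rise is not shown to come from p53. AEN, a nuclease of apoptosis, rose from 82.4 ± 6.39 to 162 ± 11.2 CPM. TIGAR, a regulator of sugar metabolism, rose by 0.74, TP53INP1 by 0.58 and the stress gene GADD45A by 0.51 on the log2 scale. Of 13 replication-dependent histone genes, 9 rose, and all 13 adjusted over the list alone (median 1.53, camera adjusted p = 4.52e-09, and adjusted p = 0.185 with an estimated correlation). Levels differed, from H2AC11, which went from 1.25 ± 0.31 to 4.26 ± 0.35 CPM, and H4C8, from 1.92 ± 0.55 to 5.54 ± 0.68 CPM, to H4C15 and H4C14, outside the fixed list and overlapping H3C15 and H3C14, which rose from 14.1 ± 1.38 to 38.3 ± 3.73 CPM and from 15.2 ± 2.04 to 39.4 ± 8.28 CPM. Histone genes are near-identical copies, so values of single members are uncertain. How fully the mRNA kit captured histone transcripts was not measured, so the rise is not shown to hold for all histone mRNA. The list of S phase and DNA replication genes was not called (4 of 34 rose and 1 fell, camera adjusted p = 0.328). In the G2/M list 5 of 33 members rose, 2 fell, and 7 rose and 2 fell adjusted over the list alone (median 0.15, camera adjusted p = 0.0111, and adjusted p = 0.185 with an estimated correlation). After GC correction the list median was 0.092 (camera adjusted p = 0.0472, and adjusted p = 0.257 with an estimated correlation). HMMR (0.43), NEK2 (0.34) and NUSAP1 (0.32) were among those that rose.

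Of 26 genes of cholesterol synthesis and uptake, 16 fell and none rose, or 19 fell and 2 rose adjusted over the list alone (median -0.35, camera adjusted p = 8.67e-08, and adjusted p = 0.185 with an estimated correlation). SREBF2, the transcription factor that drives this pathway, went from 330 ± 1.39 to 230 ± 6.27 CPM. DHCR7, which catalyses the last step of cholesterol synthesis, fell by 0.60 and SQLE, squalene epoxidase, by 0.58 on the log2 scale. In fatty acid synthesis 7 of 19 genes fell and 1 rose, or 8 and 2 adjusted over the list alone (median -0.18, camera adjusted p = 0.0054, and adjusted p = 0.349 with an estimated correlation). The desaturase gene SCD went from 1366 ± 52.3 to 903 ± 16.8 CPM, and FASN, fatty acid synthase, fell by 0.59. In glycolysis 7 of 20 genes fell, as many adjusted over the list alone (median -0.19, camera adjusted p = 0.00308, and adjusted p = 0.622 with an estimated correlation). The median was -0.12 both without YFCS replicate 1 and without control replicate 1. They included PFKL (-0.47) and the glucose transporter gene SLC2A1 (-0.46). Of 29 TGF-beta and extracellular matrix genes, 12 fell and none rose, or 16 fell and 2 rose adjusted over the list alone (median -0.26, camera adjusted p = 0.000444, and adjusted p = 0.281 with an estimated correlation). The collagen genes COL4A2 (-0.52) and COL6A1 (-0.50) and the cytokine gene TGFB1 (-0.53) were among them.

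**Figure D2:**
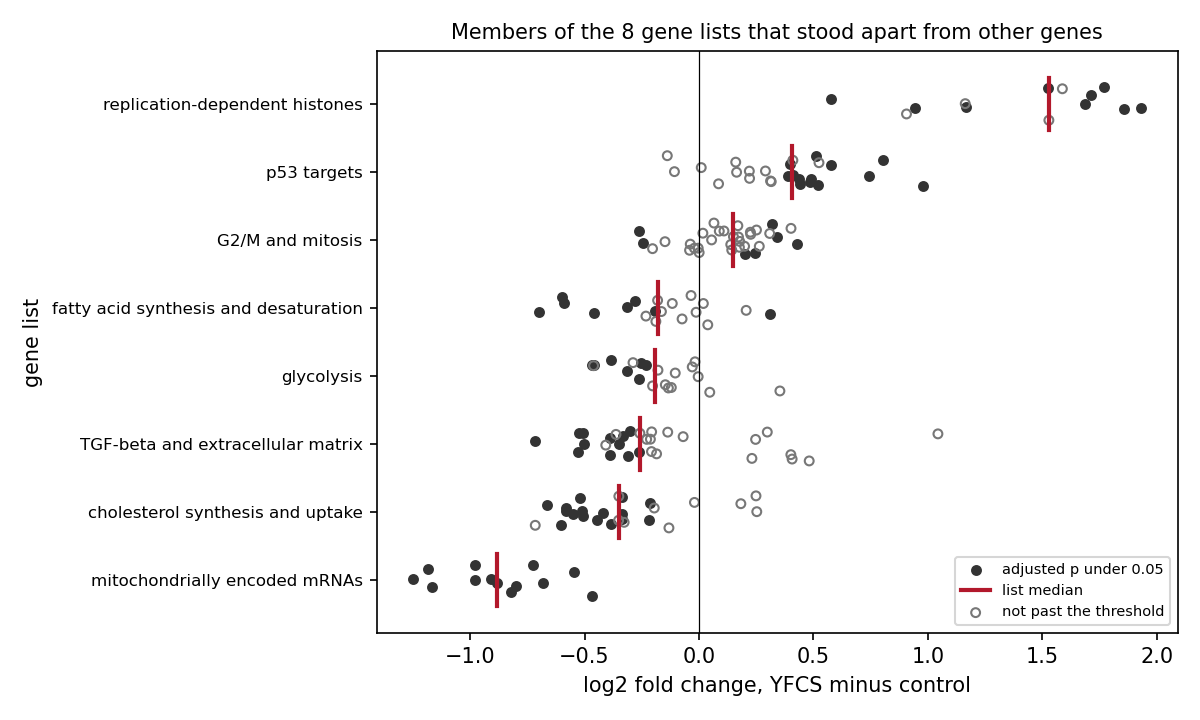
Log2 fold change (YFCS minus control, horizontal axis) of each tested member of the 8 gene lists called by camera. Filled points passed an adjusted p of 0.05, open points did not, and red bars are list medians, from -0.88 for mitochondrially encoded mRNAs to 1.53 for histones.

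Lists of innate immune response were not called by camera. Among 20 NF-kB and cytokine genes 1 rose, RELB (0.63), and the list (median 0.19, camera adjusted p = 0.0909) was called higher by fry (adjusted p = 0.0108) and by camera after GC correction (adjusted p = 0.0229). With an estimated correlation camera did not call it before GC correction (adjusted p = 0.333) or after. The fry test does not compare a list with other genes. Among 30 interferon-stimulated genes 2 rose, USP18 (0.46) and IFIT5 (0.46). Of 12 pattern recognition genes 1 rose, the mannose receptor gene MRC1, from 0.41 ± 0.19 to 1.18 ± 0.12 CPM. Of 24 heat shock genes 6 rose and none fell, among them HSPH1 (0.47) and HSPA4 (0.30), with a camera adjusted p = 0.162 for the list. ATF4 targets went both ways, with 7 higher, such as CEBPG (0.42), and 4 lower, such as SLC7A5 (-0.42), of 36. That list (camera adjusted p = 0.162) was called higher without control replicate 1 (adjusted p = 0.0344) and after GC correction (adjusted p = 0.0472). Both calls rest on the preset correlation. With all libraries and an estimated correlation its camera adjusted p was 0.819, and GC correction with an estimated correlation did not call it. Of 32 lysosome and autophagy genes 8 fell, among them the cathepsin gene CTSD (-0.67), and 4 rose. None of 73 cytosolic ribosomal protein genes passed edgeR's test, with 0 at an unadjusted p under 0.05 and 1, RPS2, called by DESeq2, and camera called their list in opposite directions without control replicate 1 (median 0.12) and without control replicate 2 (median -0.17). Those calls used the preset correlation, while the correlation estimated with all libraries was 0.856, with a camera adjusted p = 0.981. The median, mean and test of a list differed in sign for NRF2, hypoxia, lysosome and epithelial junction genes, none of them called.

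Markers of other cell types were mostly near the floor in both groups. The leukocyte list had a median of 0.64 CPM after YFCS and 0.36 CPM in controls, with 0 of 10 tested members changed by edgeR's test, 1 at an unadjusted p under 0.05 and 1 called by DESeq2, both ITGAM. None of 3 keratinocyte and 4 erythroid markers changed by edgeR's test or DESeq2, with 0 and 1 (ALAS2) at an unadjusted p under 0.05. Single markers of other lists did, named here after their values were seen: ALB (1.56), MYH3 (0.78) and ACTA1 (1.56) higher and COL3A1 (-0.72) and FLT1 (-0.38) lower. Of 15 tested markers of the line itself, EYA1 (0.28) was higher and NEFM (-0.36) and NEFL (-0.32) were lower.

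Fold changes followed the GC content of genes, with a Spearman correlation across 14727 genes of -0.35; genes are not independent replicates. In the fifth of genes with the lowest GC content 358 rose and 68 fell, and in the fifth with the highest 39 rose and 451 fell. Libraries of the same group also differed in this trend: rho was -0.36, -0.23 and -0.16 in YFCS libraries and 0.37, -0.005 and 0.34 in controls. On the 14740 features with a known GC content, 2803 were called without a correction and 2463 after the trend was removed from each library. Of 2200 changed genes with a known GC content, 1645 were still called. Decreases of some GC-rich genes named above shrank, to -0.32 for COL6A1, -0.35 for TGFB1, -0.28 for PFKL, -0.26 for SLC7A5 and -0.41 for ICAM5, all of them still called.

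**Figure D3:**
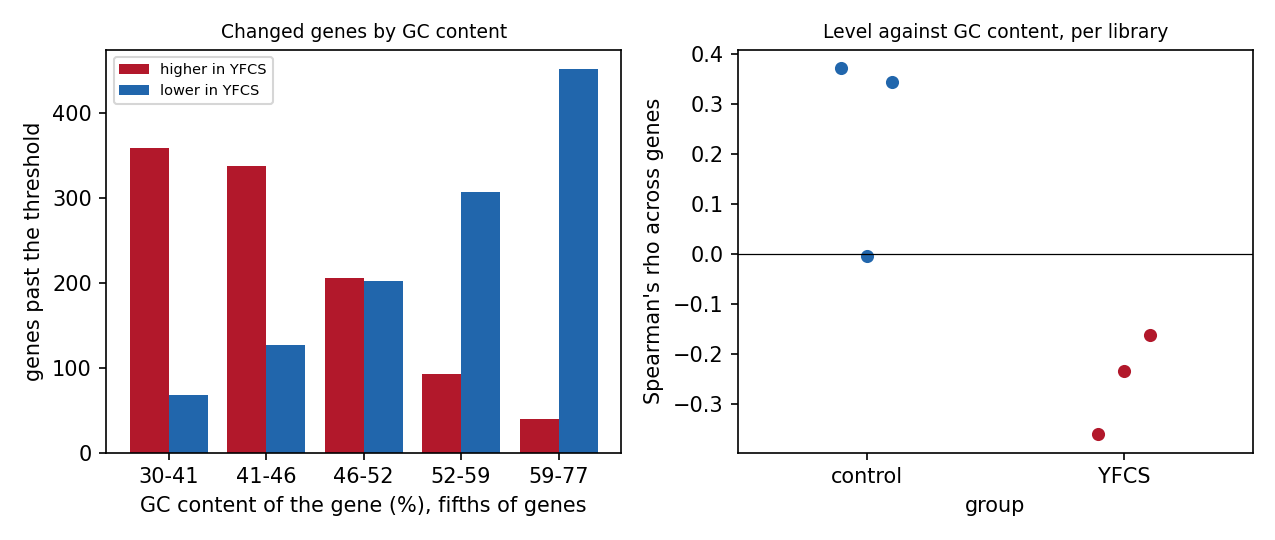
Left, genes called higher or lower after YFCS (bars) in 5 classes of GC content. Right, Spearman's rho between GC content and each gene's log2 CPM relative to its mean, 1 point per library, with YFCS libraries between -0.36 and -0.16 and controls between -0.005 and 0.37.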

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

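The GC correction, the fits limited to Ensembl genes or with altered library sizes, and the DESeq2 fit with a block were chosen after seeing the data. All 2287 changed genes kept their direction in every fit that tested them. These fits reuse the libraries in which the genes were called, so this agreement was close to fixed. Other size factors, filters, DESeq2 and the GC correction gave 2010 to 2807 changed genes and 112 to 144 at least 2-fold. With 1 library left out the counts were 423 to 2108 and 60 to 176. Fewer libraries leave fewer degrees of freedom, and 58 of the 119 named genes that changed were still called without YFCS replicate 3. With the replicate block edgeR called 0 genes, and 0 at least 2-fold, with 3902 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0801. DESeq2 with the block called 1299, and the GC correction with the block 678, of which 76 changed at least 2-fold. Libraries with the same number did not deviate together (correlations -0.079, -0.066 and -0.039), so the numbers do not pair them. Camera called 8 lists with the block, 0 lists with an estimated correlation, as many with that and GC correction, 8 to 10 with 1 library left out, and 10 after GC correction, which added the NF-kB and ATF4 lists, both higher. The median of cytosolic ribosomal protein genes ranged from -0.17 without control replicate 2 to 0.12 without control replicate 1, against -0.05 with all libraries; the cause was not tested. Planned fits on TPM and FPKM, and all transcript fits, were not run, because their treated columns match no label. Simulated 1.5-fold changes were recovered in 45.5% of cases, which limits statements on small changes. The simulation changed far fewer genes than were called in the data, so its rates of recovery and of false calls need not carry over.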

Other observations

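All tests in this part were chosen after the result was seen, except that the prediction for zinc finger genes under GC correction was written before that value was computed. Genes were also grouped by the stem of their symbol, giving 196 families of 10 or more tested members, of which camera at the preset correlation of 0.01 called 23, and 21 after GC correction. With an estimated correlation it called none, with or without GC correction (12 and 11 at an unadjusted p under 0.05), so the family calls below hold at the preset correlation only. Zinc finger genes of the ZNF family, mostly transcriptional repressors, were higher as a group: 59 of 422 rose and 7 fell (median 0.13, adjusted p = 8.89e-05, and adjusted p = 0.667 with an estimated correlation). Symbols beginning with H and a digit, nearly all histones, had a median of 0.90 (0.68 after GC correction), with 19 of 39 higher and 2 lower, H2AZ2 and H6PD, the latter not a histone. The zinc finger ZSCAN genes had a median of 0.24, with 4 of 16 higher. Axonemal dynein genes (DNAH) had a median of 0.48, with 4 of 12 higher. NBPF genes, a family of near-identical copies whose counts are uncertain, had 7 of 11 higher and a median of 0.33. Lower families included GALNT enzymes, which start O-linked glycosylation (5 of 16 fell, median -0.23), and SLC transporters (55 of 278 fell and 10 rose, median -0.14).

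The comparison of 3 with 3 libraries allows 10 splits, so no share under 0.1 can be reached. The real split gave 2287 changed genes, as many as in 1 of the 10 splits, and the highest of the others gave 7.

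MUC13 and CXCR5 were almost confined to YFCS libraries, where cells of the intestine or of the B lineage would bring their other abundant transcripts, but the median of 17 intestinal markers was 0.00114% of the MUC13 level (highest CDX2, 15.0 CPM against 16.7 in controls), and that of 11 B cell markers was 0.372% of the CXCR5 level (highest CD37, 2.74 CPM; only CD22 changed). Annotated genes within 500 kb of MUC13 held in controls 8.24% of what MUC13 gained, too little to have been the source of its reads. For CXCR5 they held 3475%, so that source stays open. BCL9L alone, which overlaps CXCR5, averaged 22.8 CPM in controls and 18.2 CPM after YFCS. Against the 49.0 CPM that CXCR5 gained, this argues against BCL9L as the whole source. Assembled loci have no position and were not searched: they lost 2980 CPM and gained 1712 CPM in sum, a net loss of 1268 CPM against the 3108 CPM that MUC13 gained (SD 339), so they could be its whole source only if nearly all of their losses went there. An introduced copy or a difference in cell stock between the groups cannot be told apart from a response to YFCS, since gene counts do not show which part of a transcript was read; 17 features, 11 of them assembled loci, had a fitted fold of 32 or more in either direction. Coverage of the untranslated exons of MUC13 would be a direct test.

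The GC trend may contribute to many of the smaller changes, and within-group SD of the library trends was 0.336 of the difference between groups, so bias and response cannot be told apart for the trend itself. After its removal the list medians were 0.39 for p53 targets, 1.65 for histones, -0.35 for cholesterol genes and -0.23 for extracellular matrix. They were -0.14 for glycolysis and -0.13 for fatty acid synthesis. All were still called at the preset correlation. For the larger shifts that outcome was close to fixed, since the trend was small. Median log2 fold changes ran from 0.087 in the class of lowest GC content to -0.16 in the highest. The shifts of p53 targets (0.40), histones (1.53), cholesterol genes (-0.35) and extracellular matrix (-0.26) lay outside that range. This size, not the kept calls, argues against GC bias as the whole cause of those shifts. Glycolysis (-0.19) and fatty acid synthesis (-0.18) had lain near that range. The fifth that spans the median GC content of fatty acid genes, 49.1%, had a median of 0.014. With the -0.13 kept after correction, this argues against GC bias as the whole cause for that list. For glycolysis (median GC content 53.2%) the fifth had a median of -0.094. Its list median was -0.12 without YFCS replicate 1, which leaves it open. With an estimated correlation none of these lists was called before the correction or after it (adjusted p = 0.139 to 0.514 after). At the preset correlation the ZNF family kept a median of 0.12 and its call (adjusted p = 0.797 with an estimated correlation). The G2/M list moved from 0.15 to 0.092 (adjusted p = 0.0472, and 0.257 with an estimated correlation), which leaves that list open.

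Mitochondrially encoded mRNAs had a median of -0.95 after GC correction and -0.88 with these genes, MUC13 and CXCR5 left out of the library sizes. Both outcomes were close to fixed in advance by the sizes given next, so neither counts as a test. Nuclear genes in the fifth that spans their median GC content of 44.3% had a median of 0.069, so the trend ran against the decrease. Mitochondrial genes held 2.34% of counts in YFCS libraries and 3.88% in controls, and MUC13 at most 0.35%, too little to shift library sizes by that much. The median of nuclear oxidative phosphorylation genes exceeded that of the mitochondrial list by 0.82 (spread between libraries 0.27), but nuclear mRNAs need not follow the number of mitochondria. Fewer mitochondria or mitochondrial DNA copies, lower transcription and lower mRNA stability therefore cannot be told apart here; the DNA copy number would separate the first from the others. Chloramphenicol, an inhibitor of mitochondrial translation present in the yeast broth, could act only if its activity differed between supernatant and control medium, which was not tested.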
